A study of Mus musculus with 12 samples.

How the data were processed

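RNA of 12 male mice was extracted with the Trizol method and hybridised to target-specific barcoded probes of a metabolic nCounter panel, per the labels' protocols. The deposited table holds, per library, a normalized signal for 736 rows, and the software, the reference genes and the background step behind this signal are not given in the sources used here. Every row name was found as a symbol in the mouse gene table used for names (736 of 736). All 12 columns were those of the 12 samples, and no other column was present. Groups came from the labels: control diet with normal water or Western diet with sugar water, crossed with wild type or knockout, 3 mice each. Replicate numbers follow the order of the samples and pair nothing. The labels give each library its own diet duration, 16 to 27 weeks, rising by 1 from library to library, whereas the growth protocol gives 16 weeks for all, so this number was not used. The mice were separate animals per the labels' ages and titles, as far as these tell.

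Within each library, values above 21 and below 3000 were whole multiples of 1 step (100% of values within 0.1 of a whole number), which gave the value of 1 count, 0.906 to 1.50, and the recovered total count. The deposited signal therefore appears as a count times 1 factor per library, with low values listed at 21. Counts below this floor are unknown, so no count model was used. Values at 21 carry no order. In most libraries the lowest count above the floor was the first whose scaled value exceeds 21, so there the floor acted on the scaled value. In Western-diet wild-type replicate 3 and knockout replicate 2 the lowest count was 21, with 1 count worth 1.50 and 1.13. There a limit on counts acted as well. A listed 21 can thus stand for any value below the lowest one above it. That was 31.6 in Western-diet wild-type replicate 3 and 21.1 to 23.7 in the other libraries. A fold change that rests on values at 21 can therefore be too small or too large. Replicates of a group differed by far more than counting noise: chi-square per degree of freedom over 538 rows above 21 in every library was 12.7 to 337 between pairs. The precision is that of 3 mice per group, and p-values measure the spread between these mice.

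Values were tested as log2(value + 1) in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 4 group means fitted over all 12 libraries and 8 residual degrees of freedom. There were 7 contrasts: diet within each genotype, genotype within each diet, both averages and the interaction. P-values were adjusted by Benjamini-Hochberg over 736 rows within each contrast, with a threshold of 0.05. Errors of fold changes are limma's moderated standard errors. Rows at 21 in all libraries have no spread, and with them the estimated prior had 0.705 degrees of freedom, against 2.42 for 670 rows above 21 in at least 3 libraries. Gene lists of pathways and cell types with at least 4 measured members were tested with fry (directional p, and the p for change in either direction), and with camera using an estimated correlation. All tests, lists, named genes and alternatives were fixed before the data were examined unless said otherwise.

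The rule for named genes took the sphingolipid list first. For the 4 simple contrasts and the interaction it then took up to 12 higher and 12 lower rows past the threshold with groups that do not overlap, or, where fewer than 5 rows passed, the 10 rows of smallest p. Fewer than 5 passed in each of these. For the averaged contrasts it took only rows past the threshold, and there were none. For any list described it took up to 4 members. Some of the genes, rows and lists taken by this rule are not reported here. Genes and rows of smallest p in the averaged contrasts, genes of smallest p among the rows from A2m to Cat, and the apolipoprotein and amino acid genes, were added after the data were seen. Whether names stand on plausible levels was checked with 148 names of genes abundant in liver or in every cell and 109 names of genes low in liver, from general knowledge and written after the data were seen. AUCs compared them in 7 blocks of rows, at offsets of 0 to 15 rows, with shuffled names for the p-values.

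Alternatives fixed in advance were centring on library medians, leaving out low rows, log2(value + 10), an intensity trend with robust variances, array weights, age as a covariate, only the 2 groups compared, camera, and leaving out each library. The low-value filter had been set at 20, and because 21 is the lowest value listed it took rows above 21 in at least 3 libraries. Added later were the rows from A2m to Cat alone, a floor of 32 in every library, and the omission of both replicates 2 of the control-diet groups. The fit was tested on simulated data of 736 rows with 200 rows changed in each of 20 simulations. For genotype on Western diet it recovered 62.2% of rows changed by a log2 of 0.5, 87.9% of those changed by 1 and 97.0% of those changed by 2, with 4.33% false calls. For the interaction it recovered 39.6%, 75.9% and 92.8%. The simulation drew independent rows, so it does not cover shifts shared by many rows of a library. Changed rows were drawn only from rows of higher mean value, so recovery of rows near 21 was not simulated. With 200 rows changed, the adjusted threshold is easier to reach than with few, so these shares can overstate recovery where few rows change.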

Results

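Expression of a panel of metabolic genes was measured with nCounter probes, a method that counts colour-coded probes bound to single RNA molecules without amplification, in total RNA of 12 male C57BL6-NJ mice. The mice fell into 4 groups of 3: wild-type mice and mice with a knockout of sphingosine kinase 2 (SphK2), each fed either a control diet with normal water or a Western diet with sugar water, in a model of early metabolic dysfunction-associated steatohepatitis (MASH). The labels name no tissue. The series asks how diet and the loss of SphK2, an enzyme that phosphorylates sphingosine to sphingosine-1-phosphate, alter metabolic gene expression in this model. The table held normalized values of 736 rows, each named by a gene symbol. The recovered total was 1138914 counts in Western-diet wild-type replicate 3 and 1702816 to 1924846 counts in the other 11 libraries. A value of 21 is the lowest listed, and 42 rows stood at 21 in all 12 libraries. Western-diet wild-type replicate 3 had 185 rows at 21, against 77 to 131 in the other libraries. Control-diet knockout mice were 250 to 259 days old and control-diet wild-type mice 231 to 232 days, so by the labels age and genotype were not separated on this diet. The labelled ages of these knockout mice and of Western-diet knockout replicate 3 (252 days) are above what the growth protocol's start ages and diet time allow, so they are in doubt.

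No row was named Sphk2 or Sphk1, so the knockout could not be checked in the libraries, and the genotypes below are those of the labels.

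Row names matched the levels of the genes they name best in the first part of the table. From A2m to Cat (111 rows) the most abundant transcripts were those of apolipoproteins and liver enzymes: Apoa2 averaged 89078 ± 13436, Apoa1 83994 ± 14068 and Cat 44603 ± 6706 (SD, n = 12). In this part, all 26 names of genes abundant in liver or in every cell stood above all 21 names of genes low in liver, which is an area under the curve (AUC) of 1 (permutation p = 0.0001, the smallest 10000 shuffles can give). The name lists and the block's end at Cat were chosen after the data were seen, which this p does not allow for. After Cat the separation was weaker or absent. The row named Gapdh stood at 21 in 11 of 12 libraries, the rows named Cd36, Cps1, Trf, Txn1 and Itgb1 stood at 21 in all 12, and the row named Ube2c averaged 187621 ± 36667. Rows from Cbl to Cyp8b1, the first block after Cat, gave an AUC of 0.740 (permutation p = 0.0052), and the 5 later blocks 0.434 to 0.643 (permutation p = 0.162 to 0.778). Rows after Cat are therefore called by the name they carry, with no function, and the genes described first in each comparison are those from A2m to Cat. Tests of single rows and counts of rows do not depend on the names, whereas tests of gene lists do.

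**Figure D1:**
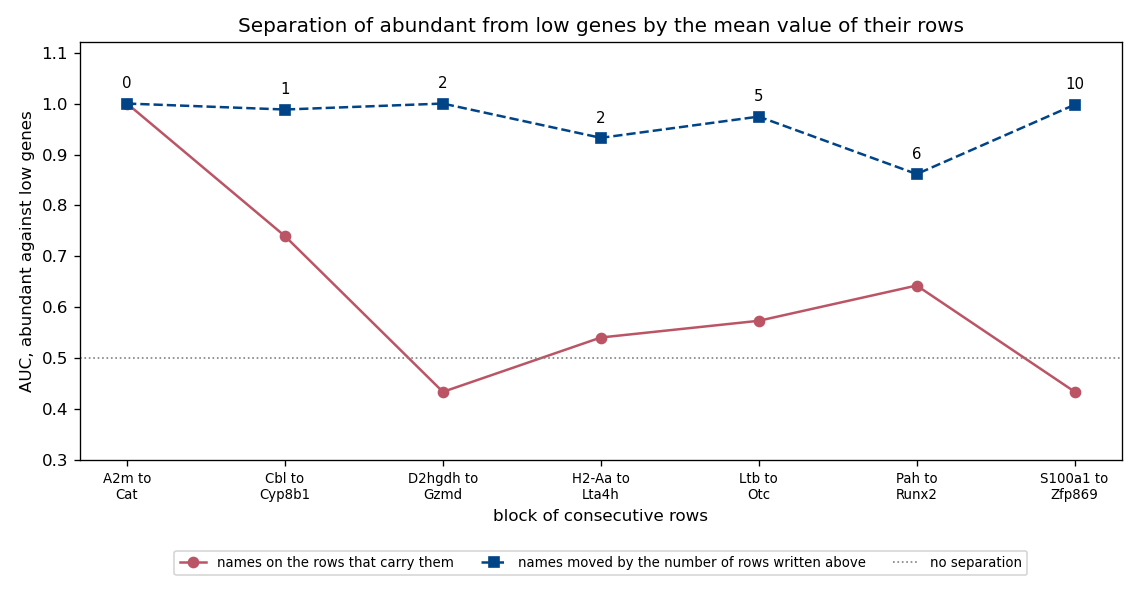
Area under the curve (AUC, y axis, no unit) with which the mean value of their rows separated names of abundant genes from names of low genes, in 7 consecutive blocks of rows (x axis). Circles are names on the rows that carry them, squares the same names moved down the table by the number of rows written above, and the dotted line marks no separation. On their own rows the names gave 1 for A2m to Cat and 0.434 to 0.740 in the 6 later blocks.

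The knockout was compared with the wild type on Western diet. Apom, the apolipoprotein that carries sphingosine-1-phosphate on high-density lipoprotein, had 2059 ± 155 in knockout and 4924 ± 854 in wild-type mice (mean ± SD, n = 3 each), a log2 fold change of -1.25 ± 0.27 (SE). Atf4, a transcription factor of the integrated stress response, had 1083 ± 71.2 and 1612 ± 74.9, a log2 fold change of -0.57 ± 0.14. Apoe, an apolipoprotein of remnant particles, had 89635 ± 10651 and 62301 ± 4480, and Acadl, the mitochondrial long-chain acyl-CoA dehydrogenase, 3616 ± 290 and 2720 ± 387. Atg2b, a lipid-transfer protein of autophagosome formation, had a log2 fold change of -0.36 ± 0.07, and Akt2, a kinase of insulin signalling, of -0.27 ± 0.06. These 6 genes, 4 lower and 2 higher in knockout mice, passed limma's test when adjusted over the 111 rows from A2m to Cat alone (adjusted p = 0.0476 each), a restriction chosen after the data were seen. Over all 736 rows none of the 6 passed (adjusted p = 0.0824 to 0.0861). Each of the 6 separated the groups with no overlap between the 3 knockout and the 3 wild-type mice.

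Other genes in this part did not pass, and some of them had larger fold changes. Apoa4, an apolipoprotein of chylomicrons and high-density lipoprotein, had 32805 ± 11236 in Western-diet knockout mice (range 19838 to 39648) and 2160 ± 555 in Western-diet wild-type mice (range 1564 to 2662), a log2 fold change of 3.89 ± 1.17 (adjusted p = 0.074 over the 111 rows). The error is pooled over all 4 groups, so it is not the spread of the Western-diet mice alone. On control diet Apoa4 spread widely, from 2685 to 33899 in knockout and 2071 to 27043 in wild-type mice. It passed over the 111 rows without both control-diet replicates 2, which were left out because of their values. Acmsd, which turns the kynurenine pathway away from NAD synthesis, had 93.6 ± 26.5 in Western-diet knockout and 361 ± 65.9 in Western-diet wild-type mice (-1.96 ± 0.50, adjusted p = 0.0509). Ass1, the urea cycle's argininosuccinate synthase, had 19979 ± 4911 and 34073 ± 1260 (-0.80 ± 0.25, adjusted p = 0.0802). Asns, asparagine synthetase, was listed at 21 in all 3 Western-diet knockout libraries and at 29.6 to 120 in Western-diet wild-type libraries. Cacng7, a calcium channel subunit, had a log2 fold change of 1.10 ± 0.27, Atox1, a copper chaperone, of 0.30 ± 0.08, and Bad, a pro-apoptotic Bcl-2 family member, of -0.28 ± 0.07. Acat1, the mitochondrial acetyl-CoA acetyltransferase, had a log2 fold change of 0.61 ± 0.17, and Acaa2, the mitochondrial acyl-CoA thiolase, one of 0.10 ± 0.11 that turned negative with median centring.

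Over all 736 rows, limma called 1 row in this comparison, the row named Zfp65, with 411 ± 15.2 in knockout and 330 ± 10.9 in wild-type mice (log2 fold change 0.32 ± 0.04, adjusted p = 0.0292, higher in 3 of 3 mice than in any wild-type mouse). At an unadjusted p under 0.05 there were 154 rows, 91 higher and 63 lower. The groups did not overlap in 173 rows (23.5%), where chance gives 10%. Here and below, this 10% is for rows without ties, and ties at 21 lower it. Rows also vary together, so the share can lie far from 10% by chance. Among the next rows by p were those named Slc3a1 (1.16 ± 0.21), Slc2a1 (0.58 ± 0.11), Pklr (0.66 ± 0.14), Prkaa1 (0.27 ± 0.06), Eme1 (-1.65 ± 0.35) and Cd3d (1.97 ± 0.42), all with an adjusted p of 0.0824, which did not pass. The mean of the library medians was 0.16 (log2) higher in knockout than in wild-type libraries, while the median log2 fold change over rows was 0.03. Centring on library medians therefore takes off more than the typical row changed. With each library centred on its median, no row passed, the row named Zfp65 had a log2 fold change of 0.15, and 6 of the 111 rows passed, of which Apom and Atf4 were shared with the 6 above. The count over all rows was 21 without control-diet wild-type replicate 2, 15 without Western-diet wild-type replicate 2, 4 without control-diet knockout replicate 2, 1 without control-diet knockout replicate 1 and 0 without any other library. Among the 111 rows it was 11 without Western-diet wild-type replicate 2, 8 without control-diet wild-type replicate 2, 0 to 2 without any of the other 10 libraries, and 0 with an intensity trend and robust variances.

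**Figure D2:**
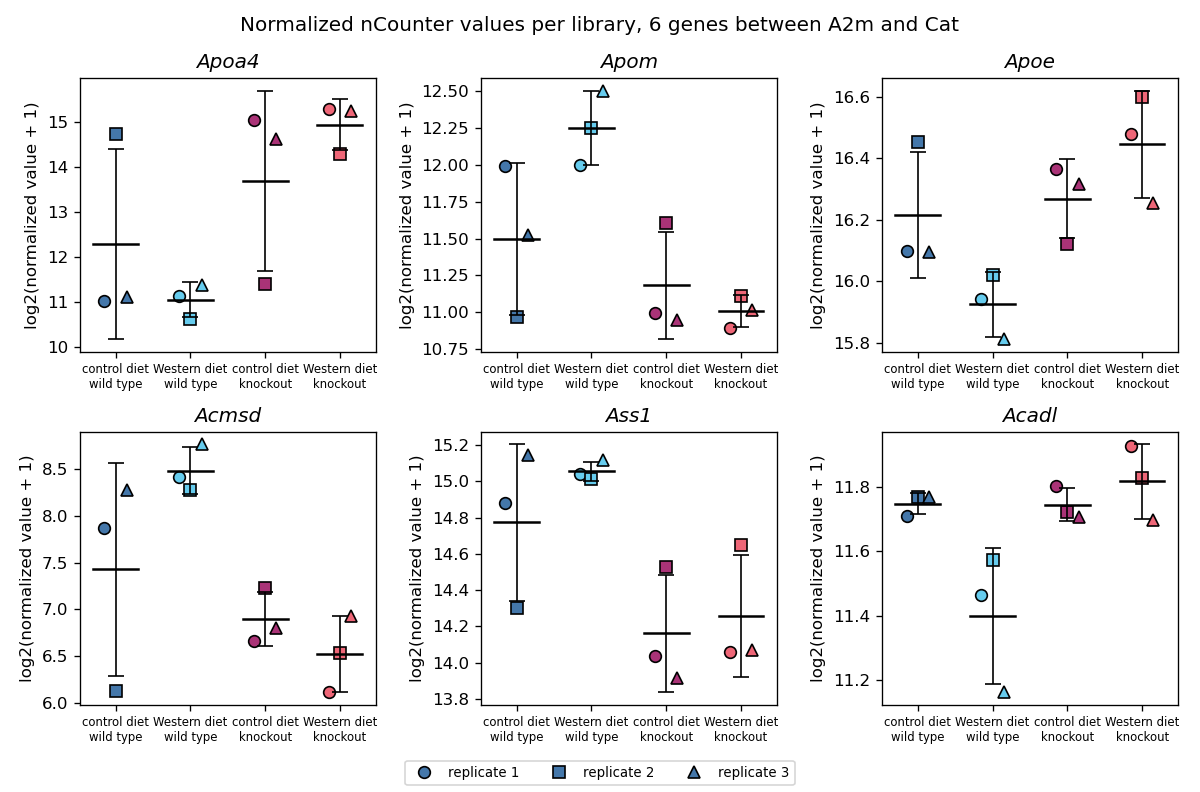
Values of 6 genes in the 12 libraries, as log2 of the normalized value plus 1 (y axis), by diet and genotype (x axis). Each symbol is 1 mouse, the wide bar the mean of 3 and the whiskers ± 1 SD. Apoa4 was 27043 in control-diet wild-type replicate 2 and 2685 in control-diet knockout replicate 2, each nearer the other genotype.

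On control diet, no row passed limma's test between knockout and wild-type mice (0 of 736 rows, and 35 at an unadjusted p under 0.05, 21 higher and 14 lower). The groups did not overlap in 49 rows (6.66%, where chance gives 10%). Among genes from A2m to Cat, Bhmt, the betaine-homocysteine methyltransferase, had 35343 ± 7225 in knockout and 50465 ± 2179 in wild-type mice (mean ± SD, n = 3 each; log2 fold change -0.53 ± 0.19, adjusted p = 0.65). Ass1 had 18647 ± 4388 and 28829 ± 8086 (-0.61 ± 0.25), and Ampd2, an AMP deaminase, had a log2 fold change of -0.28 ± 0.10, Acap2 of 0.34 ± 0.14, Atf7 of 0.22 ± 0.08 and A2m of -0.42 ± 0.18. None of these passed (adjusted p = 0.65 each). The rows of smallest p after Cat were those named Ttr (0.63 ± 0.13), Ccl19 (0.81 ± 0.22), Gmps (0.57 ± 0.15) and Prkag2 (0.35 ± 0.09), which did not pass either. In control-diet wild-type libraries, the rows named Ttr and Ccl19 were at 21 throughout and that named Gmps in replicate 1. A2m was at 21 in control-diet knockout replicates 1 and 2. The fold changes and errors of these rows rest in part on that floor.

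In each of these 2 groups, 1 library lay apart from the other 2. Chi-square per degree of freedom was 329 and 337 in pairs with control-diet knockout replicate 2, and 12.7 in the remaining pair. It was 163 and 139 in pairs with control-diet wild-type replicate 2, and 56.5 in the remaining pair. Pairs of Western-diet libraries reached 163 in wild-type and 182 in knockout mice, so by this measure the control-diet wild-type spread was not unusually wide. Apoa4 was 2071 and 2208 in control-diet wild-type replicates 1 and 3 and 27043 in replicate 2, while it was 33899 and 25298 in control-diet knockout replicates 1 and 3 and 2685 in replicate 2. Its log2 fold change on control diet was 1.41 ± 1.17 (adjusted p = 0.681). Without both replicates 2, left out because of their values, limma called 26 rows on control diet (16 higher and 10 lower in knockout mice), 37 on Western diet (22 and 15) and 155 averaged over diets (108 and 47). Because the 2 libraries were chosen by their values, these counts are not those of an independent test. The first principal component of 515 rows with a mean above 50 held 66.1% of the variance. Along it the knockout libraries had 5.73 to 10.1, except control-diet replicate 2 with -4.91 and Western-diet replicate 2 with -1.99, and the wild-type libraries -8.01 to -3.95, except control-diet replicate 2 with 1.91.

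**Figure D3:**
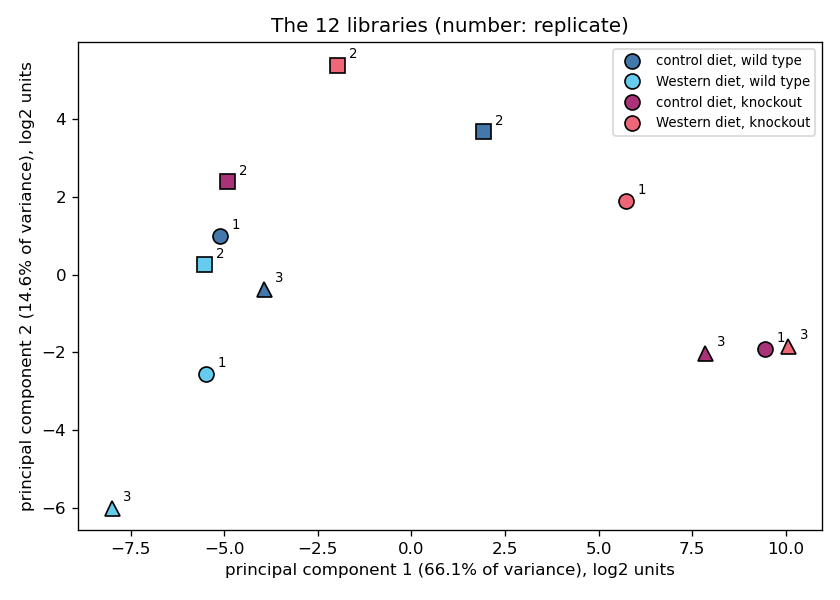
The 12 libraries on the first (x axis, 66.1% of variance) and second (y axis, 14.6%) principal components of the log2 values, in log2 units. Colour gives diet and genotype, and the symbol and number give the replicate. Control-diet knockout replicate 2 lies at -4.91 on the first component, among the wild-type libraries.

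Averaged over both diets, no row passed limma's test between knockout and wild-type mice (0 of 736), with 188 rows at an unadjusted p under 0.05, 119 higher and 69 lower. From A2m to Cat, the genes of smallest p were Atg2b (-0.21 ± 0.05, log2 fold change ± SE), Apom (-0.78 ± 0.19), Ass1 (-0.70 ± 0.18), Cacng7 (0.77 ± 0.19), Atox1 (0.22 ± 0.06), Acmsd (-1.24 ± 0.35) and Bhmt2, a second homocysteine methyltransferase gene (-0.36 ± 0.10). Atf4 had -0.32 ± 0.10, Apoe 0.29 ± 0.09, and Apoa4 2.65 ± 0.83. Their adjusted p over all rows was 0.148 to 0.149, so none passed. Rows after Cat of smallest p were those named Zfp65 (0.19 ± 0.03), Prkaa1 (0.21 ± 0.04), Prkag2 (0.35 ± 0.07), Pklr (0.48 ± 0.10) and Ccl19 (0.75 ± 0.15), with adjusted p of 0.118 to 0.144. The row named Ccl19 was at 21 in all wild-type libraries. The count of calls was 132 without control-diet knockout replicate 2, 20 without control-diet wild-type replicate 2 and 0 without any other library. Adjusted over the 111 rows from A2m to Cat, where 0 passed with all libraries, it was 19 without control-diet knockout replicate 2, 14 without Western-diet knockout replicate 2, 11 without control-diet wild-type replicate 2, 2 without Western-diet wild-type replicate 2, 0 without any other library, and 5 with median centring (Acmsd, Apom, Ass1, Atf4 and Cacng7). Apom, Ass1, Atg2b, Bhmt2 and Cacng7 passed without each of the first 3 of these libraries. These 3 lay apart from the others of their genotype on the first principal component (-4.91, -1.99 and 1.91). Leaving out such a library can raise the genotype difference or lower the spread by construction. Passing without each of them is therefore no independent support.

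Western diet was compared with control diet in wild-type mice. No row passed (0 of 736 by limma, 49 at an unadjusted p under 0.05, 22 higher and 27 lower), and 81 rows (11.0%) did not overlap between the groups, where chance gives 10%. Acadl had 2720 ± 387 on Western and 3441 ± 79.2 on control diet, and Acat1 6037 ± 1423 and 8000 ± 896 (mean ± SD, n = 3 each). Their log2 fold changes were -0.35 ± 0.10 and -0.43 ± 0.17 (SE), and that of Acaa2 -0.17 ± 0.11. Adjusted p over all rows was 0.563 to 0.842, so none passed. Apom had 4924 ± 854 on Western and 3011 ± 1039 on control diet (0.75 ± 0.27), Bad 0.28 ± 0.07, Atg2b 0.26 ± 0.07, Asns 1.30 ± 0.46, Aoc1, a diamine oxidase, -0.65 ± 0.20 and Brca2 -0.66 ± 0.22, none past the threshold. Aoc1 and Brca2 were at 21 in Western-diet wild-type replicate 3, where 21 can stand for any value below 31.6, so their fold changes can be too large. With every value raised to at least 32 they were -0.37 (Aoc1, diet in wild type: log2 fold change) and -0.38 (Brca2, diet in wild type: log2 fold change). Asns was at 21 in control-diet wild-type replicates 1 and 2, so its fold change and error rest in part on that floor. After Cat, small p were those of the rows named Zfp65 (-0.27 ± 0.04) and Ctsd (-0.56 ± 0.10), with adjusted p of 0.0999 and 0.139. The count was 1 without control-diet wild-type replicate 1 and 1 without Western-diet wild-type replicate 2. Adjusted over the 111 rows from A2m to Cat, 0 passed with all libraries, 6 without Western-diet wild-type replicate 2 (Acadl, Acat1, Aoc1, Asns, Bad and Brca2) and 1 without control-diet wild-type replicate 3.

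In knockout mice, no row passed between Western diet and control diet (0 of 736 by limma, and 17 at an unadjusted p under 0.05, 8 higher and 9 lower), and 44 rows (5.98%) did not overlap, where chance gives 10%. By the labels, Western-diet knockout mice were 217, 221 and 252 days old and control-diet knockout mice 250 to 259 days. Age was therefore only partly separated from diet here, which also enters the interaction. Akt2 had 465 ± 25.7 on Western and 534 ± 31.5 on control diet (mean ± SD, n = 3 each; log2 fold change -0.20 ± 0.06). Brca2 had -0.55 ± 0.22, Ampd2 0.24 ± 0.10 and Ak5, an adenylate kinase, -0.53 ± 0.22. With every value raised to at least 32, Ak5, diet in knockout: log2 fold change was -0.20. Apoa4 had 32805 ± 11236 on Western and 20627 ± 16123 on control diet (1.24 ± 1.17). Rows after Cat of small p included those named Prkab2 (-0.60 ± 0.14), Cyp8b1 (-0.65 ± 0.19) and Ndufa12 (0.17 ± 0.05). Each of these had an adjusted p of 1. The row named Prkab2 was at 21 in Western-diet knockout replicates 1 and 2. Adjusted over the 111 rows, Ak5 passed without Western-diet knockout replicate 1. Its values in Western-diet knockout replicates 2 and 3 were 21 and 24.2, so this pass rests on the floor.

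Averaged over genotypes, no row passed for diet (0 of 736 by limma, 18 at an unadjusted p under 0.05, 10 higher and 8 lower on Western diet). Brca2 had the smallest p from A2m to Cat (-0.60 ± 0.15, adjusted p = 0.652), followed by Aoc1 (-0.37 ± 0.14). Adjusted over the 111 rows, Brca2 passed without Western-diet wild-type replicate 2. Both genes rest in part on the value at 21 in Western-diet wild-type replicate 3. The rows named Zfp65 (-0.14 ± 0.03), Prkab2 (-0.44 ± 0.10) and Ctsd (-0.31 ± 0.07) had an adjusted p of 0.501. That named Prkab2 was at 21 in Western-diet knockout replicates 1 and 2.

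The difference between the diet effects in the 2 genotypes was tested as an interaction. No row passed (0 of 736 by limma, 44 at an unadjusted p under 0.05, 22 above and 22 below 0). Acadl had a diet effect of -0.35 ± 0.10 in wild-type and 0.07 ± 0.10 in knockout mice, an interaction of 0.42 ± 0.14 (adjusted p = 0.549). Apoe had -0.29 ± 0.12 and 0.18 ± 0.12, an interaction of 0.47 ± 0.18, and Apom 0.75 ± 0.27 and -0.18 ± 0.27, an interaction of -0.93 ± 0.38. In knockout mice the diet effects of Acadl and Apoe turned negative with age as a covariate, and that of Apom turned positive without control-diet knockout replicate 2. The interaction was -0.34 ± 0.08 for Akt2, -0.34 ± 0.10 for Bad, -0.29 ± 0.10 for Atg2b, -0.50 ± 0.19 for Atf4 and 0.57 ± 0.24 for Acat1. Adjusted p was 0.46 to 0.789 for these genes. Adjusted over the 111 rows, Bad passed without Western-diet wild-type replicate 2 and Ak5 without Western-diet knockout replicate 1. The remaining Western-diet knockout values of Ak5 were 21 and 24.2, at or next to the floor, so its pass rests on that floor. After Cat, the row named Zfp65 had 0.26 ± 0.06 (adjusted p = 0.46).

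Gene lists were tested by the names of their rows, and 32 of the 42 lists had at least 4 members in the table. Over all rows, none passed the directional fry test in any of the 7 comparisons, and none passed camera with an estimated correlation. At an unadjusted fry p under 0.05 there were 3 lists for diet in wild-type mice, 7 for genotype on Western diet, 7 for genotype averaged over diets, 1 for the interaction and 0 for the other 3 comparisons. The smallest adjusted p were 0.178 for genotype averaged over diets and 0.225 for genotype on Western diet. On Western diet the rows named for cytotoxic and NK cell markers had 13 of 15 members above 0 with a median log2 fold change of 0.40 (fry adjusted p = 0.225; camera adjusted p = 0.988 with an estimated correlation). All 15 of these rows lie after Cat. The test of change in either direction passed for 10 lists on Western diet and for 15 averaged over diets, and most members of these lists lie after Cat. Many names after Cat stand on levels unlike those of their genes. Here and below, list tests over all rows therefore cannot decide whether a pathway or cell type changed. Within the rows from A2m to Cat, a restriction chosen after the data were seen, no list fixed in advance passed the directional fry test. There, 4 of 4 fatty acid oxidation genes were higher in knockout mice on Western diet, against 1 of 4 on control diet.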

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

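Tests of the rows from A2m to Cat, of a floor of 32 and without both control-diet replicates 2 were chosen after the results were seen. The single call for genotype on Western diet (1 row) was lost, giving 0, with median centring, without low rows, with age as a covariate, with only the 2 groups compared and with a floor of 32. It remained 1 with log2(value + 10) and with trend and robust variances, and was 6 within the rows from A2m to Cat. Leaving out 1 library gave 0 to 21 genes for genotype on Western diet, 0 to 3 on control diet, 0 to 132 averaged over diets (with 0 to 6 gene lists), 0 to 1 for diet in wild type and 0 to 1 for the interaction. It gave 0 for diet in knockout and diet averaged over genotypes, and 0 gene lists in the other 6 comparisons.

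Array weights, whose estimation did not converge, called 1 gene for diet in wild type, 26 for diet in knockout, 195 for genotype on control diet, 326 for genotype on Western diet, 3 for diet averaged, 371 for genotype averaged and 19 for the interaction. They called 14 gene lists for genotype on Western diet and 19 averaged over diets. They ranged from 0.220 for control-diet knockout replicate 2 to 7.45 for Western-diet knockout replicate 1. Age as a covariate gave 2 genes for diet in knockout. Only the 2 groups compared gave 1 gene list for genotype on Western diet. Without both control-diet replicates 2 there were 26 genes and 1 list for genotype on control diet, 37 and 1 on Western diet, and 155 and 4 averaged over diets. The cause of these changes was not tested, except that leaving out the 2 libraries lowers the spread by construction.

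Among 2802 values of named genes under alternatives, 2599 kept direction and side of the threshold, 185 came to pass, 13 no longer passed, all of the row named Zfp65 on Western diet, and 5 changed sign. These were Acaa2, genotype on Western diet: log2 fold change -0.063 with median centring; Acadl, diet in knockout: log2 fold change -0.0687 and Apoe, diet in knockout: log2 fold change -0.0285 with age as a covariate; and Apom, diet in knockout: log2 fold change 0.0345 without control-diet knockout replicate 2, alone or with wild-type replicate 2. The last was -0.18 ± 0.27 (SE) with all libraries and -0.293 without control-diet knockout replicate 3. None of these values passed. With all libraries and over all rows, the only named value that passed was that of the row named Zfp65 on Western diet. For the other named values, keeping the side of the threshold meant still not passing. Centring on housekeeping genes was not run, since 0 of the 20 listed genes are among the row names, and no count model was run. Depth limits low rows most in Western-diet wild-type replicate 3, where the lowest value above 21 was 31.6.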

Other observations

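Lists of apolipoproteins, of amino acid and urea cycle enzymes and of alcohol, aldehyde and ketone oxidoreductases were written after the data were seen, from genes between A2m and Cat, as were the tests of the row names and of the 2 control-diet libraries below. Because their genes were seen first, no test of these lists is given, and the values below come from single genes that did not pass over all rows. In the list of amino acid breakdown and the urea cycle, knockout-minus-wild-type log2 fold changes averaged over diets were -0.82 ± 0.25 (SE) for Asl, argininosuccinate lyase, -0.80 ± 0.30 for Agxt, alanine-glyoxylate aminotransferase, and -0.59 ± 0.19 for Arg1, arginase. Among the apolipoproteins, Apoc2, the cofactor of lipoprotein lipase, had 1.36 ± 0.47 on Western diet (adjusted p = 0.161).

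Many row names after Cat stood on levels unlike those of the genes they name. Names moved down by 1 offset per block separated abundant from low genes in all 6 later blocks (AUC 0.862 to 1, permutation p of 0.0005 to 0.0375, where 0.0005 is the smallest 2000 shuffles can give), at offsets of 1, 2, 2, 5, 6 and 10 rows. A candidate explanation is therefore that the names are displaced against the values by a number of rows that grows down the table. Probes that failed would leave low genes low, yet 14 names of low genes after Cat were among the 100 highest rows, against 0 up to Cat. Immune or dividing cells would leave abundant genes high, yet 35.2% of 122 abundant names after Cat had a mean below 100, against 0 of 26 up to Cat. What caused this, and whether the deposit or a later copy of the table carries it, stays open, and no row was renamed.

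Of the control-diet libraries, 1 of each genotype lay nearer the other genotype. On an axis from the mean of Western-diet wild-type libraries (0) to that of Western-diet knockout libraries (1), control-diet wild-type replicate 2 scored 0.80 and replicates 1 and 3 scored 0.22 and 0.26, while control-diet knockout replicate 2 scored 0.28 and replicates 1 and 3 scored 1.25 and 1.09. Labelled age does not account for wild-type replicate 2, since control-diet wild-type replicates 1 and 2 were both 231 days old and differed by 0.579. Control-diet knockout replicate 2 had no partner of equal age. Its label gives 253 days, those of replicates 1 and 3 give 259 and 250, and these ages are in doubt. Library medians do not account for the pattern either. After median centring, the score of wild-type replicate 2 still exceeded that of knockout replicate 2 by 0.524. Other kinds of scaling were not tested. An exchange of the 2 libraries' labels may account for the pattern, since both stay on the other genotype's side after median centring (0.80 and 0.28) and without the 50 rows of largest difference (0.70 and 0.26). It cannot be told apart from a state of the mice that the labels do not give: 1 of the 6 Western-diet libraries, knockout replicate 2, also lay on the other side when left out of the axis (0.37, with 0.39 after centring and 0.33 without the 50 rows), so a library can lie there without a partner, and no row named Sphk2 was analysed here.

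Other splits of the same samples were fitted for each comparison, counting rows and lists at an unadjusted p under 0.05. With 3 mice against 3 there are 10 splits, too few for a share under 0.05. The real split gave 49 rows for diet in wild type (highest other 65; 2 splits as large, the real one included), 17 for diet in knockout (248; 8 splits), 35 for genotype on control diet (197; 4 splits) and 154 for genotype on Western diet (91; 1 split, the real one). The lists were 3 (3; 2 splits), 0 (16; 10 splits), 0 (7; 10 splits) and 7 (3; 1 split) in the same order. The split with 197 rows puts control-diet wild-type replicate 2 with the knockout libraries and knockout replicate 2 with the wild-type ones, which points to the structure of the samples described above. Of 100 drawn splits, chance was not excluded for genotype averaged over diets (188 rows, highest other 272, 5 splits as large; 7 lists, 14, 6 splits), for diet averaged over genotypes (18 rows, 210, 69 splits; 0 lists, 11, 100 splits) or for the interaction (44 rows, 174, 23 splits; 1 list, 8, 58 splits).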
